A study of Mus musculus with 12 samples.

How the data were processed

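Total RNA of bone marrow-derived macrophages was taken up in Trizol, turned into biotin-labelled cDNA and hybridized to 12 Affymetrix whole-transcript arrays, per the labels' protocols. The arrays came in 4 groups of 3, PBS and hepcidin at 1 h and at 3 h, as the sample labels name them. The deposited table holds 1 expression value for each of 25429 probe sets on each array. The submitters' processing notes name RMA and Partek but give no version, and the part each played is not given in the sources used here. The deposited values were used as log2 values, since RMA returns log2 and their range fits that scale, although no label writes the log base. No label names a genome build, so no coordinates are printed, and the RefSeq gene table of assembly GRCm38.p6 served only for gene names, Entrez IDs and gene classes.

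Of the probe sets, 24675 had a symbol in the gene table, each gene with 1 probe set, and these were tested. The other 754 probe sets are not named here and entered only 1 alternative and 1 count. No filter on expression was applied.

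Differences were computed in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes), as a linear model with 4 group means, 8 residual degrees of freedom and 4.11 prior degrees of freedom. The family held 5 comparisons: hepcidin against PBS at 1 h, hepcidin against PBS at 3 h, the average of both effects, the difference between them, and PBS at 3 h against PBS at 1 h. P-values were adjusted across genes within each comparison by Benjamini and Hochberg, and a gene passed, and is said to have risen or fallen, at an adjusted p under 0.05. The comparisons at 1 h and 3 h share no array. Errors are limma's moderated standard errors, and group values are means with the SD of 3 arrays.

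The gene lists and the rule for naming genes were written before the data were examined. Named are the 12 largest rises and falls past the threshold with groups that do not overlap at 1 h, at 3 h and between the PBS groups, the 6 largest for the average and for the difference, up to 4 members of each list, and Slc40a1, Tfrc, Socs3, Il17ra, Tnf, Il6 and Il1b whatever their result. Of these last genes, Il17ra is printed at 1 h only and the others at least at 1 h and 3 h. Predicted gene models and numbered clones were counted and not named. Of 28 fixed lists, 27 had at least 5 members on the array, and the list of mitochondrially encoded genes had none. They cover immediate early genes, NF-kB feedback and subunit genes, inflammatory cytokines and chemokines, inflammatory effectors and receptors, type I interferon, STAT3, iron handling, NRF2 and metals, hypoxia, ER stress and amino acid response, heat shock, cholesterol synthesis, LXR, growth factor withdrawal and FOXO, p53, alternative activation, the cell cycle, macrophage identity, markers of neutrophils, dendritic cells, lymphocytes, erythroid cells, fibroblasts, osteoclasts and mast cells, cytosolic ribosomal proteins and histones. Lists were tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists of a comparison. A second adjustment ran over the members of each list alone. Lists overlap: 6 of 20 STAT3 members, 4 of 22 FOXO members, 4 of 20 p53 members, 3 of 28 immediate early genes and 2 of 28 iron genes stand in another list.

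The alternatives were the replicate number as a block, a trended and robust prior, an unmoderated linear model, genes above the median mean, quantile normalization again, median centring, all probe sets, array weights, a fit of only the groups compared, a fold minimum of 1.5, an adjusted p under 0.1, and each array left out in turn. For lists they also included camera with an estimated correlation, camera on ranks and fry. The STAT3 list without shared members was added after the data had been seen.

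The procedure was tested on simulated data in which 200 of 24675 genes were changed. Each gene had its mean over all arrays and limma's moderated variance, the same in all 4 groups. A log2 change of 0.7 was recovered in 91.0% of cases at 1 h, 82.1% at 3 h and 94.0% between the PBS groups, and one of 0.35 in 26.9%, 23.9% and 29.9%. One of 1.4 was recovered in 100%, 95.5% and 100%. False calls made up 3.33%, 2.19% and 5.70% of all calls, and camera found the shifted list in each comparison with 0 of the unshifted lists called. The simulated genes varied independently of each other, and the 200 changes were placed in genes above the median mean. The simulation therefore cannot show how often lists of correlated genes are called falsely, nor the recovery among dimmer genes. The simulated comparisons differed only in their random draws, so they cannot show a difference in recovery between comparisons. The measured median SD was 0.117 with hepcidin and 0.094 with PBS at 3 h.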

Results

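Gene expression was measured in bone marrow-derived macrophages, primary mouse cells grown from marrow precursors in a conditioned medium that supplies M-CSF, after hepcidin or PBS was added to the wells. Hepcidin is the peptide hormone of iron balance, which binds the iron exporter ferroportin, encoded by Slc40a1, and leads to its degradation. The 12 arrays form 4 groups of 3, PBS and hepcidin at 1 h and PBS and hepcidin at 3 h. The cells were moved to DMEM alone, without the M-CSF source, for 1 h before the peptide was added. The study asked which genes the peptide changes at each time, and the series title ties hepcidin to inflammation. The dose is not settled, because the labels give 1 µg/ml in the growth protocol and 10 µg/ml in the treatment protocol, and the latter speaks of 1 h only. No label states that the samples of a group came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

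The median expression of an array lay between 4.84 and 4.94 on the log2 scale, and arrays of the same group correlated across probe sets with r between 0.994 and 0.997. The number of arrays, 3 per group, limits the precision, and the median SE of a log2 difference between 2 groups was 0.10. Principal component 1, with 29.5% of the variance, placed the hepcidin arrays of 3 h at 18.4 to 29.8 and those of 1 h at 0.427 to 1.66. The PBS arrays of both times lay at -15.2 to -10.7.

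**Figure D1:**
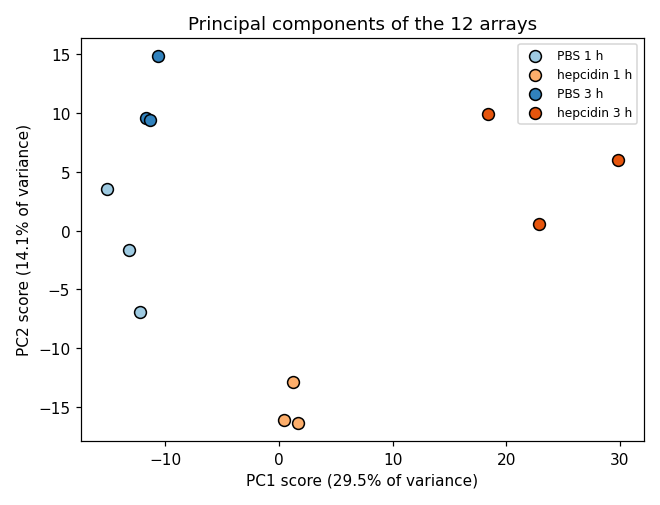
Scores of the 12 arrays (points, coloured by group) on principal component 1 (x axis, 29.5% of the variance, no unit) and principal component 2 (y axis, 14.1%, no unit). The 3 hepcidin arrays of 3 h lie at 18.4 to 29.8 on component 1, to the right of the 3 hepcidin arrays of 1 h and of the 6 PBS arrays.

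Within 1 h, macrophages given hepcidin had raised inflammatory genes and the feedback genes of NF-kB. Cxcl2 (Entrez gene 20310), a chemokine that attracts neutrophils, rose by 6.12 on the log2 scale (SE 0.20), from 4.12 ± 0.27 to 10.25 ± 0.13 (SD, n = 3 arrays in each group). Acod1 (Entrez gene 16365), the enzyme that makes itaconate, rose 12.6-fold (log2 change 3.66, SE 0.15). Tnf (Entrez gene 21926) rose 12.1-fold (3.60, SE 0.13) and Il1b (Entrez gene 16176) rose by 2.96 (SE 0.13). No fold is given for Cxcl2 and Il1b, whose PBS values lay below the array median of 4.87, where background enters the signal. Background makes a change read smaller, so the log2 changes of such genes are not exact and their order is not measured. This also holds for Mir146 at 1 h and for Cxcl3, Fpr2, Ifi205, Gbp5 and Cp at 3 h. In limma the adjusted p was 1.1e-08 for Cxcl2, 5.69e-08 for Acod1, 1.45e-08 for Tnf and 1.39e-07 for Il1b. Nfkbiz, Cxcl1, Cd69, Tnfaip3, Mir146, Gpr84, Ptgs2 and Tnfsf9 followed with log2 changes from 3.08 down to 2.44.

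Of 24675 genes tested, 138 passed the threshold at 1 h, 130 higher and 8 lower with hepcidin, and all 51 genes that also changed at least 2-fold were higher. An unadjusted p under 0.05 was found for 1683 genes, 6.82% of those tested. In each of the 138 genes the 3 arrays of one group lay above the 3 arrays of the other, an order that 12.3% of all genes had and that chance gives to 10% of genes. The falls were small, and their number was 3 without PBS 1 h replicate 1, PBS 1 h replicate 2 or hepcidin 1 h replicate 2 and 17 without hepcidin 1 h replicate 1. Zfp970 changed by -0.76 on the log2 scale, Mir5104 by -0.70, Mir1933 by -0.62, Hmga2-ps1 by -0.51, Mir3070b by -0.41 and the potassium channel gene Kcng2 by -0.39. The other 2 were predicted gene models. Of the 39 genes past the threshold that the naming rule chose, 31 kept their call whichever array was left out. Fas, Hspa1a, Hspa1b, Nupr1, Kcng2, Mir3070b, Mir1933 and Zfp970 lost it without at least 1 array.

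Of the 15 NF-kB feedback and subunit genes on the array, 14 rose at 1 h, or 15 adjusted over the list alone (camera adjusted p = 2.11e-64). Nfkbiz stood at 3.08 on the log2 scale, Tnfaip3 at 2.81, Nfkbia at 2.39 and Nfkbie at 2.37. Among 28 inflammatory cytokines and chemokines 9 rose, or 13 adjusted over the list alone, with Cxcl2, Tnf, Cxcl1 and Il1b among them (camera adjusted p = 7.67e-23). Il6 changed by 0.03 (SE 0.09, adjusted p = 0.992). Among 21 inflammatory effectors and receptors 10 rose, or 12 up and 1 down adjusted over the list alone (camera adjusted p = 2.10e-25). These include Ptgs2, the inducible cyclooxygenase, at 2.58, the adhesion molecule gene Icam1 at 1.76 and Tlr2 at 1.67. Of 28 immediate early genes 8 rose, or 17 adjusted over the list alone (camera adjusted p = 1.83e-20). Among them were Ier3 at 1.98, Zfp36, which destabilises cytokine mRNAs, at 1.51, and Junb at 1.09.

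The STAT3 target genes also shifted up at 1 h, with 6 of 20 up and 6 adjusted over the list alone (camera adjusted p = 2.63e-12). Pim1 rose by 1.83, the cytokine signalling inhibitor Socs3 by 1.77 (SE 0.13, 3.41-fold) and Bcl3 by 1.32. In this list 6 members stand in another fixed list, and the 14 others, taken alone after the data had been seen, gave a camera adjusted p of 1.51e-07. Their median log2 change was only 0.089, and Pim1 and Socs3 are among them, so this p does not show that most of the 14 shifted. Il17ra changed by 0.02 (adjusted p = 0.996).

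A smaller upward shift was called in 3 further lists at 1 h. Of 20 p53 target genes 2 rose, Btg2, an antiproliferative gene, at 0.98 and the death receptor gene Fas at 0.95, and 2 adjusted over the list alone (camera adjusted p = 0.00587). In the ER stress and amino acid response list (camera adjusted p = 0.00544, adjusted p = 0.0529 with an estimated correlation) 2 of 21 rose, or 5 adjusted over the list alone. They were the transcription factor gene Cebpb at 0.60 and Nupr1 at 0.47. Of 22 growth factor withdrawal and FOXO targets 3 rose, Gadd45b at 1.00, Gadd45a at 0.75 and Cited2 at 0.63, or 4 adjusted over the list alone. Its camera adjusted p was 0.00587, with adjusted p = 0.169 with an estimated correlation and 0.0556 without PBS 1 h replicate 1. The other 6 of the 8 lists past the threshold at 1 h kept their call with an estimated correlation.

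Iron genes moved little at 1 h. Slc40a1 (Entrez gene 53945) changed by -0.09 (SE 0.07, adjusted p = 0.893) and the transferrin receptor gene Tfrc by -0.03 (SE 0.12, adjusted p = 0.995). The iron importer gene Slc11a2 rose by 0.73 (SE 0.10, adjusted p = 0.00238). It was the 1 member of 28 iron handling genes past the threshold, and 1 adjusted over the list alone (camera adjusted p = 0.51).

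Of 30 type I interferon response genes Irf1 alone rose at 1 h, by 1.36 on the log2 scale, and 1 adjusted over the list alone (camera adjusted p = 0.0991). This list passed without PBS 1 h replicate 2 (0.00133) or hepcidin 1 h replicate 1 (2.65e-04). In the heat shock list 2 of 16 rose, Hspa1a at 0.88 and Hspa1b at 0.63, and 2 adjusted over the list alone. Its median was -0.04, its mean 0.05 and its camera direction up (adjusted p = 0.712). Limma called 0 members in the NRF2 and metal response, hypoxia, cholesterol synthesis, LXR target and alternative activation lists, and 0 adjusted over each list alone. It also called 0 in the cell cycle, macrophage identity, osteoclast, ribosomal protein and histone lists, on both counts. As whole lists, hypoxia passed without PBS 1 h replicate 3 (0.0315), and the cell cycle (3.14e-04) and histone lists (4.25e-04) without hepcidin 1 h replicate 1.

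Markers of other cell types did not pass in limma at 1 h. This held for neutrophils and granulocyte precursors (0 of 18), dendritic cells (0 of 17), lymphocytes (0 of 16), erythroid cells (0 of 11), fibroblasts and stroma (0 of 18) and mast cells and basophils (0 of 12). Adjusted over the list alone, 1 dendritic cell marker was lower and 1 mast cell marker higher. The median log2 change was 0.06 for the neutrophil list and -0.09 for the dendritic cell list. The fibroblast list had a median of -0.04 and a mean of 0.02 with the test pointing down, and it passed without hepcidin 1 h replicate 3 (0.00461). The mast cell list had a median of -0.04 and a mean of 0.01 with the test pointing up. The osteoclast list had a median and a mean of 0.01 with the test pointing down.

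At 3 h inflammatory genes were raised again and many other genes fell. Acod1 rose 61.6-fold (log2 change 5.94, SE 0.15, n = 3 arrays in each group) and Cxcl2 by 5.27 on the log2 scale (SE 0.20). Gpr84, a receptor for medium-chain fatty acids, rose 19.6-fold (4.29, SE 0.13) and Il1b by 4.12 on the log2 scale (SE 0.13). In limma these 4 genes had adjusted p-values of 6.87e-10, 2.67e-08, 3.80e-09 and 5.52e-09. Cxcl3, Fpr2, Ptgs2, Cxcl10, Slc7a11, Cd69, Fas and Tarm1 rose by log2 changes from 3.74 down to 2.69. The largest fall was that of the ubiquitin ligase gene Rnf144b, 2.87-fold lower (-1.52, SE 0.07, adjusted p = 1.09e-07). P2ry1, a receptor for ADP, was 2.76-fold lower (-1.47, SE 0.08, adjusted p = 2.47e-07). Fam214a, Angptl4, Lbh, Rgs2, Arhgap25, Hpgd, Olfr111, Abcd2, Snx24 and Gpr183 fell by log2 changes from -1.48 to -1.27. The fall of Hpgd, -1.32, stands beside a rise of 1.15 in PBS from 1 h to 3 h.

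**Figure D2:**
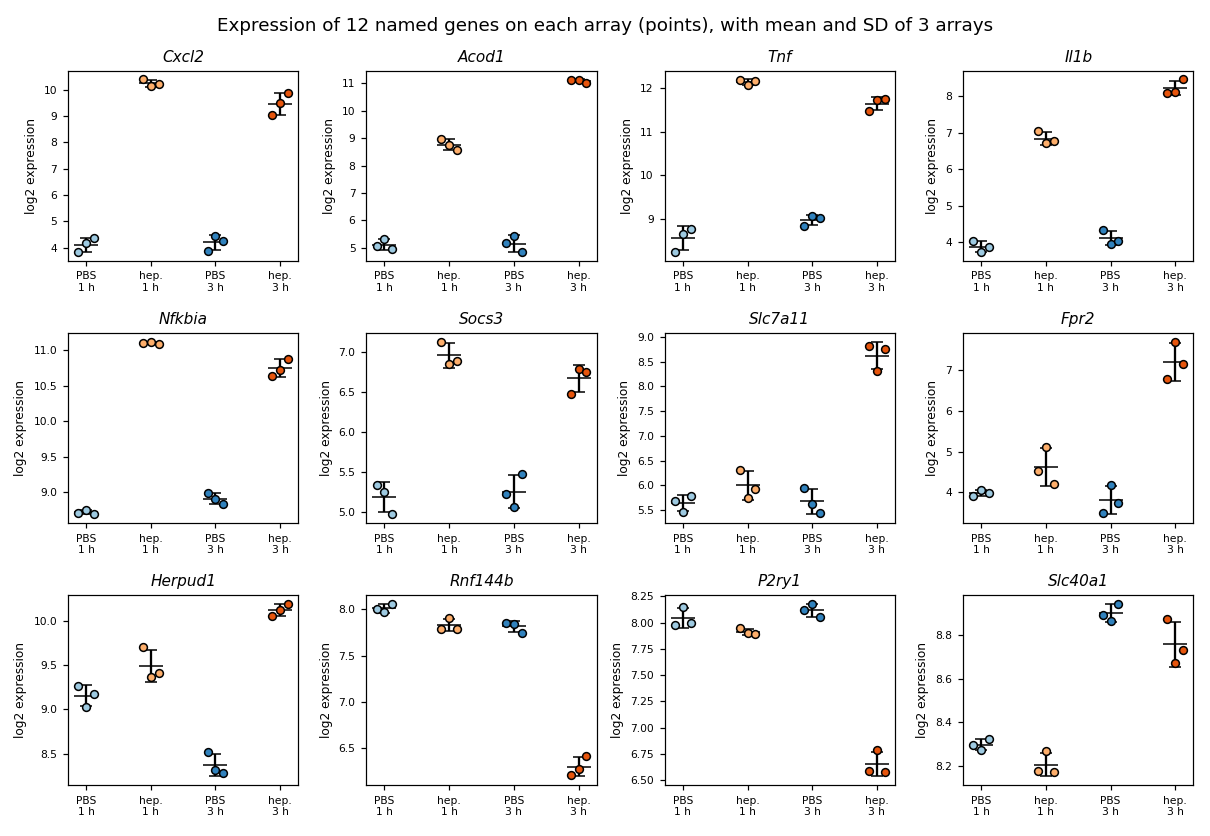
Expression of 12 named genes on each array (y axis, log2 expression; points are arrays, lines the mean and SD of 3 arrays) in the 4 groups (x axis; hep. is hepcidin). Cxcl2 lies at 4.12 on average with PBS at 1 h, 10.25 with hepcidin at 1 h and 9.47 with hepcidin at 3 h, while Slc40a1 lies at 8.30 and 8.20 at 1 h and at 8.90 and 8.76 at 3 h with PBS and with hepcidin.

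At 3 h 1316 genes passed, 692 higher and 624 lower, and 165 of them changed at least 2-fold, 130 up and 35 down. In 1314 of the 1316 the 2 groups did not overlap, as in 21.7% of all genes against 10% by chance. An unadjusted p under 0.05 was found for 4166 genes. The count fell to 851 without PBS 3 h replicate 2 and to 837 without PBS 3 h replicate 3, and was 805 with only these 2 groups in the fit. Of all 1316 genes, 702 kept their call whichever array was left out. Of the 80 that the naming rule chose, 66 kept their call whichever array was left out. Mmp9, Ifit1, Slc2a1, Nr1h3, Srxn1, Ero1a, Mvd, Prdx1, Mxi1, Ndrg1, Clec7a, Trp53inp1, Flvcr1 and Abca9 did not, and of the other genes given below as past the threshold Klf10, Lpar1 and Lpar4 did not.

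The inflammatory lists were again up at 3 h. NF-kB feedback and subunit genes rose in 14 of 15 members, and 14 adjusted over the list alone (camera adjusted p = 2.88e-35). Nfkbie and Tnfaip3 both stood at 1.99, Nfkbia at 1.84 and the adaptor gene Traf1 at 1.80. Inflammatory cytokines and chemokines rose in 13 of 28 members, or 17 adjusted over the list alone (camera adjusted p = 2.28e-17). Among them Tnf rose by 2.67 (6.38-fold) and Cxcl10 by 2.95, and Il6 changed by 0.18 (adjusted p = 0.311). Inflammatory effectors and receptors rose in 14 of 21 members and fell in 1, Tlr4 at -0.42, or 17 and 1 adjusted over the list alone (camera adjusted p = 7.65e-25). Ptgs2 stood at 3.25, Icam1 at 2.56, Clec4e, a C-type lectin receptor, at 2.46 and Nos2, the inducible nitric oxide synthase, at 1.07.

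STAT3 targets rose in 8 of 20 members at 3 h and fell in 1, Il6ra at -0.42, with the same counts adjusted over the list alone. Their camera adjusted p was 7.50e-08, with adjusted p = 0.0525 with an estimated correlation. Cebpd stood at 1.70, Pim1 at 1.56 and Socs3 at 1.42 (SE 0.13, 2.68-fold). The 14 STAT3 targets that no other list holds gave a camera adjusted p of 6.56e-06, at a median log2 change of 0.23. They were tested only at the preset correlation, so this p does not answer the loss with an estimated one. Cebpd, Pim1 and Socs3 are among the 14, so it does not show that most of them shifted.

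Stress genes shifted too. Of 21 ER stress and amino acid response genes 7 rose, or 10 up and 1 down adjusted over the list alone (camera adjusted p = 1.68e-06). They include Herpud1, a gene of ER-associated degradation, at 1.76 (SE 0.10), Nupr1 at 0.997, Cebpb at 0.97 and the glutathione-degrading enzyme gene Chac1 at 0.75. Of 17 NRF2 and metal response genes 4 rose, or 5 adjusted over the list alone (camera adjusted p = 0.00292, adjusted p = 0.077 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 2.95 (SE 0.18, 7.73-fold), Txnrd1 by 0.54, Srxn1 by 0.38 and Prdx1 by 0.28, and Hmox1 changed by 0.05 (adjusted p = 0.870).

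Growth factor withdrawal and FOXO targets went the other way at 3 h, with 11 of 22 down and 3 up, or 13 and 4 adjusted over the list alone. The camera adjusted p was 4.10e-05, and the adjusted p = 0.0539 with an estimated correlation. Fbxo32, a muscle atrophy ubiquitin ligase gene, fell by 0.92 on the log2 scale, Tob1 by 0.83 and Klf2 by 0.74, while Trib1 rose by 1.04. The cell cycle list shifted down by a median of -0.13 with 0 of 31 members past limma's threshold and 0 adjusted over the list alone. Its camera adjusted p was 0.0245, with adjusted p = 0.711 with an estimated correlation. Without PBS 3 h replicate 1, hepcidin 3 h replicate 2 or hepcidin 3 h replicate 3 it was 0.582, 0.0614 and 0.695. With an estimated correlation 4 of the 8 lists past the threshold at 3 h kept their call.

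Iron handling as a list did not pass at 3 h (camera adjusted p = 0.378), but 3 of its 28 members rose and 2 fell, or 4 and 4 adjusted over the list alone. Slc11a2 rose 2.61-fold (log2 change 1.39, SE 0.10, adjusted p = 2.69e-06) and the ferroxidase gene Cp by 1.36 (SE 0.13, adjusted p = 3.84e-05). The metal transporter gene Slc39a14 rose by 0.62, and Steap3 fell by 0.46 and the heme exporter gene Flvcr1 by 0.47. Slc40a1 changed by -0.14 (SE 0.07, adjusted p = 0.324) and Tfrc by -0.16 (SE 0.12, adjusted p = 0.555). Lcn2, which encodes a siderophore-binding protein, changed by 1.82 (SE 0.50, adjusted p = 0.0571).

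Among 30 type I interferon response genes 7 rose at 3 h, or 9 up and 1 down adjusted over the list alone. Ifi205 stood at 2.45, Gbp5 at 1.86, Gbp2 at 1.14 and Ifit1 at 0.95. The list did not pass (camera adjusted p = 0.0781) unless PBS 3 h replicate 2 (9.22e-05) or hepcidin 3 h replicate 3 (0.00771) was left out. Ifnb1 changed by 0.18 (adjusted p = 0.353). Among 28 immediate early genes 7 rose and 3 fell, or 12 and 4 adjusted over the list alone, and the fallers were the factors Klf4 at -1.02, Klf2 at -0.74 and Klf10 at -0.50. This list (camera adjusted p = 0.0712) passed without PBS 1 h replicate 1 (0.0492), PBS 3 h replicate 2 (0.0315), PBS 3 h replicate 3 (0.0197) or hepcidin 3 h replicate 1 (0.0340).

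Macrophage identity genes split at 3 h, with 2 up and 1 down of 22, or 3 and 2 adjusted over the list alone. The LPS co-receptor gene Cd14 at 0.80 and Spi1 at 0.30 were up, and the efferocytosis receptor gene Mertk was down at -1.08. Of 20 alternative activation genes Tgm2 rose, by 0.57, and 3 fell, Irf4 by 0.55, Clec7a by 0.44 and the mannose receptor gene Mrc1 by 0.35, with 1 and 3 adjusted over the list alone. In PBS from 1 h to 3 h Tgm2 changed by -0.68 and Clec7a by 0.66. Hypoxia genes rose in 2 and fell in 3 of 23, with Slc2a1 at 0.64 and Ndrg1 at -0.40, and 2 and 3 adjusted over the list alone. The p53 targets rose in 2 and fell in 3 of 20, or 4 and 3 adjusted over the list alone, with Fas at 2.69 and Sesn1 at -0.66. LXR targets rose in 1 and fell in 2 of 13, or 1 and 3 adjusted over the list alone, with Nr1h3 at 0.50 and Scd2 at -0.70. The LXR list passed without PBS 3 h replicate 1 (0.0492).

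Heat shock genes rose in 2 of 16 at 3 h, Hspa1b at 1.30 and Hspa1a at 1.10, and 2 adjusted over the list alone. Cholesterol synthesis rose in 1 of 20, Mvd at 0.29, and 1 adjusted over the list alone, and the list passed without hepcidin 3 h replicate 3 (0.0151). Osteoclast markers rose in 1, Mmp9 at 1.25, and fell in 1, Nfatc1 at -0.49, of 11, or 1 and 3 adjusted over the list alone. Limma called 0 of 38 ribosomal protein genes, 0 of 23 histone genes and 0 of the neutrophil (18), dendritic cell (17), lymphocyte (16), erythroid (11), fibroblast (18) and mast cell (12) markers. Adjusted over the list alone, 1 dendritic cell marker was up and 1 down. Median and mean differed in sign for heat shock (-0.02 and 0.17), dendritic cell markers (0.02 and -0.03), erythroid markers (-0.04 and 0.01) and osteoclast markers (-0.06 and 0.02), none of which passed.

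**Figure D3:**
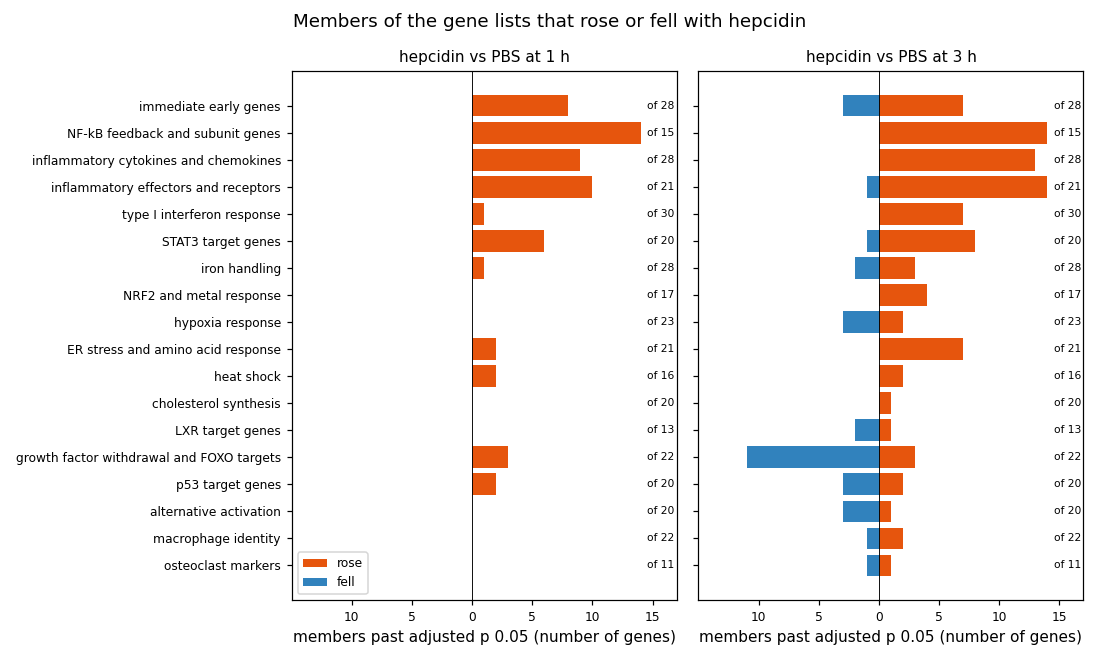
Number of members past the threshold with hepcidin (x axis, number of genes; orange bars to the right rose, blue bars to the left fell) in 18 fixed gene lists (y axis) at 1 h (left) and 3 h (right), with the list's size at the right edge. NF-kB feedback and subunit genes rose in 14 of 15 members at both times, and growth factor withdrawal and FOXO targets fell in 11 of 22 members at 3 h.

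Most genes raised at 1 h were also raised at 3 h. Of the 130 genes higher at 1 h, 111 were higher at 3 h, including Cxcl2, Acod1, Tnf and Il1b, where independent lists would share 3.65. At both times 4 genes were lower, against 0.202. The comparisons at 1 h and 3 h have no array in common. Across genes, which are not independent replicates, the log2 changes at the 2 times correlated with Pearson r = 0.460 and Spearman rho = 0.189. Of the genes called at 1 h, 98.6% had the same sign at 3 h, and of those called at 3 h, 79.9% had the same sign at 1 h.

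Averaged over both times, 988 genes passed, 577 higher and 411 lower. Of those that changed at least 2-fold 82 were higher and 1 lower, and at 1.5-fold 184 and 45. Acod1 rose by 4.80, Gpr84 by 3.45, Tnf by 3.14 and Cd69 by 2.94 on the log2 scale. Cxcl2 at 5.69 and Il1b at 3.54 also rose, with PBS values near background that leave the size inexact. Among the named genes the falls were led by the G protein regulator gene Rgs2 at -0.95, Lpar6 at -0.93, Arrdc3 at -0.86, Rnf144b at -0.85, Olfr111 at -0.83 and Nlrp1b at -0.83. For the averaged effect 9 lists passed and 6 kept their call with an estimated correlation. Type I interferon (camera adjusted p = 0.0273, adjusted p = 0.624 with an estimated correlation) and NRF2 genes (0.00389, adjusted p = 0.0856 with an estimated correlation) did not. Nor did FOXO targets (0.0295, adjusted p = 0.29 with an estimated correlation). The interferon call was also lost without PBS 1 h replicate 1 (0.136), hepcidin 1 h replicate 2 (0.107), hepcidin 1 h replicate 3 (0.0812), PBS 3 h replicate 1 (0.108), PBS 3 h replicate 3 (0.217) or hepcidin 3 h replicate 2 (0.121). The FOXO call was lost without PBS 1 h replicate 3 (0.0715), PBS 3 h replicate 2 (0.0538) or hepcidin 3 h replicate 1 (0.0746). The cell cycle list gained a call without PBS 1 h replicate 2 (0.0199) or 3 (0.00635), hepcidin 1 h replicate 1 (9.34e-05), PBS 3 h replicate 2 (0.0344) or 3 (0.00623), or hepcidin 3 h replicate 1 (6.24e-04). LXR targets gained one without PBS 1 h replicate 1 (0.0393), histones without hepcidin 1 h replicate 1 (0.00914) and cholesterol synthesis without hepcidin 3 h replicate 3 (0.0361).

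**Figure D4:**
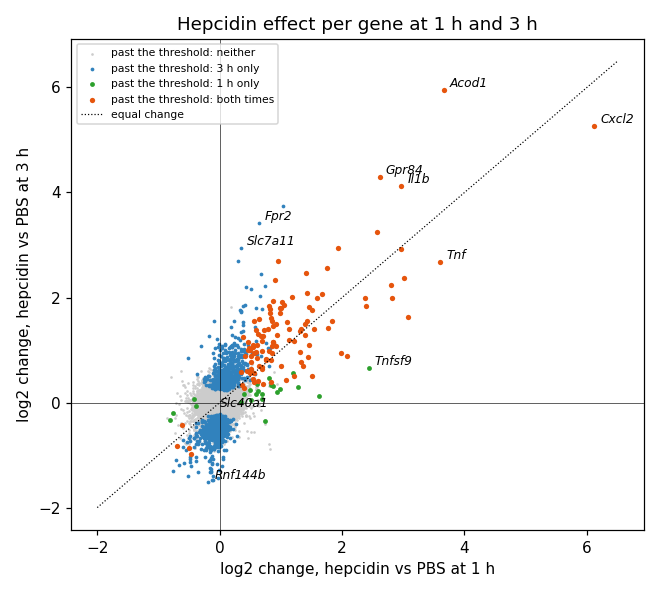
Log2 change with hepcidin against PBS at 1 h (x axis, log2) and at 3 h (y axis, log2) for each of the 24675 genes (points, coloured by the times at which they passed the threshold; the dotted line marks equal change). Acod1 lies above the line at 3.66 and 5.94, Cxcl2 below it at 6.12 and 5.27, and Rnf144b among the genes called lower at 3 h at -1.52.

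The effect itself differed between the times for named genes in both directions. Slc7a11 gained 2.60 on the log2 scale from 1 h to 3 h (SE 0.25), Tarm1 2.39 (SE 0.21) and Acod1 2.28 (SE 0.21). In limma these 3 had adjusted p-values of 4.17e-04, 3.13e-04 and 3.13e-04. Fpr2, a receptor for formyl peptides, at 2.77 (adjusted p = 0.00331) and Cxcl3 at 2.71 (adjusted p = 0.00962) also passed, but only their hepcidin groups of 3 h lay above the array median of 4.87, so the size is inexact. Tnfsf9, the ligand of 4-1BB, differed by -1.78 (SE 0.26, adjusted p = 0.00671), Nfkbiz by -1.44, Zfp36 by -0.997 and Tnf by -0.92. In all, 254 genes differed, 129 with a more positive and 125 with a more negative effect at 3 h, or 31 and 17 of those that differed at least 2-fold. Of the 130 genes higher at 1 h the effect was larger at 3 h in 26 and smaller in 15. Of the 624 genes lower at 3 h the fall was larger than at 1 h in 107.

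The count of genes whose effect differed was 144 without PBS 1 h replicate 2, 159 without PBS 1 h replicate 3, 143 without hepcidin 1 h replicate 2 and 158 without hepcidin 1 h replicate 3. It was 141 without PBS 3 h replicate 2 and 145 without PBS 3 h replicate 3. Tnf, Gbp5, Cp, Nfkb2, Slc11a2, Cd14, Nfatc1, Junb, Irf1, Foxo3, Btg2, Irs2 and Ier3 each lost the call without at least 1 array, as did Icam1, Nfkbia, Rgs2 and Arhgap25. Of all 254 genes, 117 kept it whichever array was left out.

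By list, the effect on immediate early genes was lower at 3 h than at 1 h (camera adjusted p = 7.15e-09), with 0 members up and 4 down of 28, or 2 and 12 adjusted over the list alone. The same held for FOXO targets (3.61e-11), with 0 and 4 of 22, or 0 and 11 adjusted over the list alone. It was higher for inflammatory effectors and receptors (5.45e-10), with 5 and 0 of 21, or 10 and 1 adjusted over the list alone. In the ER stress list (5.92e-04) 1 of 21 was higher, Herpud1 at 1.42, or 7 adjusted over the list alone. In the NRF2 list (camera adjusted p = 0.0301, adjusted p = 0.239 with an estimated correlation) 1 of 17 was higher, Slc7a11, or 2 adjusted over the list alone. The NRF2 call was lost without PBS 1 h replicate 3 (0.124), hepcidin 1 h replicate 3 (0.106), PBS 3 h replicate 3 (0.0674), hepcidin 3 h replicate 1 (0.0571) or hepcidin 3 h replicate 2 (0.0829). The cell cycle list gained a call without PBS 1 h replicate 1 (4.28e-04), hepcidin 1 h replicate 3 (0.00203), PBS 3 h replicate 3 (0.00825) or hepcidin 3 h replicate 1 (7.27e-04). Hypoxia gained one without PBS 1 h replicate 3 (0.0247), fibroblast markers without hepcidin 1 h replicate 3 (0.0153) and type I interferon without PBS 3 h replicate 2 (0.0152). The other 4 lists kept their call with an estimated correlation. The NF-kB list did not pass as a whole, with 3 up and 2 down of 15, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.537).

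The PBS groups give the change that time in the wells brought without the peptide, and ER stress genes fell. Chac1 was 3.28-fold lower at 3 h than at 1 h (log2 change -1.71, SE 0.11, n = 3 arrays in each group, limma adjusted p = 8.03e-05). The stress gene Sesn2 changed by -1.09 (SE 0.10, adjusted p = 0.00194), and Herpud1 by -0.79. Cdc6 at -0.69 and the replication helicase genes Mcm3 and Mcm2 at -0.65 and -0.59 passed as single genes, but Cdc6 and Mcm3 lost the call without at least 1 array. Plxdc2 rose by 1.41 (SE 0.14, adjusted p = 0.00194), the prostaglandin-degrading enzyme gene Hpgd by 1.15, Mirlet7c-1 by 1.05, Lifr by 0.90 and Fos by 0.89. Slc40a1, the ferroportin gene, rose by 0.61 (SE 0.07, adjusted p = 0.00416), from 8.30 ± 0.03 to 8.90 ± 0.04 on the log2 scale. All 3 arrays of 3 h lay above those of 1 h.

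In PBS 111 genes differed between the times, 51 higher and 60 lower at 3 h, or 3 and 2 of those that changed at least 2-fold. In all 111 the groups did not overlap, as in 17.7% of all genes against 10% by chance, and 2619 genes had an unadjusted p under 0.05. The count was 33, 26 and 30 without PBS 1 h replicate 1, 2 and 3, and 40, 30 and 23 without PBS 3 h replicate 1, 2 and 3. It was 60 without hepcidin 1 h replicate 2, and 7 with only these 2 groups in the fit. Plxdc2, Ptgir, Npas4, Slc40a1, Mcm2, Tgm2, Ifrd1, Sesn2 and Chac1, 9 of the 32 genes past the threshold that the naming rule chose, kept their call whichever array was left out. The other 23 did not, with Hpgd, Fos, Herpud1, Mcm3 and Cdc6 among them.

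The ER stress and amino acid response list fell in 7 of 21 members with time in PBS, or 1 up and 11 down adjusted over the list alone (camera adjusted p = 2.47e-11). It alone of 7 lists kept its call with an estimated correlation (0.00322). The PBS arrays of 3 h serve both this comparison and that of hepcidin at 3 h, in which the list rose, so chance values in them enter the 2 with opposite sign. The same caution applies to Hpgd, Clec7a, Tgm2 and the FOXO list, which also changed in opposite directions in these comparisons. Ptgs2 rose in both. Herpud1 stood at 9.16 ± 0.12 in PBS and 9.49 ± 0.18 in hepcidin at 1 h, and at 8.37 ± 0.13 and 10.13 ± 0.07 at 3 h (log2, SD, n = 3). Chac1 stood at 7.82 ± 0.16 and 8.20 ± 0.11 at 1 h and at 6.11 ± 0.17 and 6.86 ± 0.15 at 3 h.

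The other lists past the threshold in PBS were called in camera with few members or none past limma's threshold. NF-kB genes shifted up (camera adjusted p = 4.81e-04, adjusted p = 0.506 with an estimated correlation), with 0 of 15 members past and 5 adjusted over the list alone. NRF2 genes (0.0389, adjusted p = 0.388 with an estimated correlation) had 0 of 17, and 3 up adjusted over the list alone. FOXO targets were up (0.0463, adjusted p = 0.388 with an estimated correlation), with 1 of 22, Cited2, and 3 up and 1 down adjusted over the list alone. Cholesterol synthesis was down (3.59e-04, adjusted p = 0.343 with an estimated correlation), with 1 of 20, Sqle at -0.53, and 3 adjusted over the list alone. The cell cycle was down (1.58e-04, adjusted p = 0.766 with an estimated correlation), with 3 of 31, and 8 adjusted over the list alone. Ribosomal proteins were down (0.0389, adjusted p = 0.388 with an estimated correlation), with 0 of 38, and 0 adjusted over the list alone.

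Without PBS 1 h replicate 1 the cell cycle (0.207), ribosomal (0.173), NRF2 (0.173) and FOXO (0.207) calls in PBS were lost. Without PBS 1 h replicate 2 the ribosomal (0.0658), NRF2 (0.0847) and FOXO (0.0677) calls were lost, and without PBS 3 h replicate 2 the same 3 (0.0837, 0.0787 and 0.177). The NRF2 call was also lost without PBS 3 h replicate 1 (0.0614). The FOXO call was lost without PBS 3 h replicate 3 (0.113) or hepcidin 1 h replicate 1 (0.0530), 2 (0.0591) or 3 (0.0562). Calls were gained by type I interferon without PBS 1 h replicate 1 (0.00803) or PBS 3 h replicate 2 (3.98e-05), and by immediate early genes without PBS 1 h replicate 3 (0.0281) or PBS 3 h replicate 1 (0.0248). Neutrophil markers gained one without the same 2 arrays (0.0281 and 0.0441), and LXR targets without PBS 3 h replicate 1 (0.0441). Hypoxia gained one without PBS 1 h replicate 2 (0.0352) or PBS 3 h replicate 3 (0.0375), and fibroblast and mast cell markers without the latter (0.0375 each).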

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

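The tests of lipopolysaccharide and of granulocytes were chosen after the result was seen, and the other tests here before it. The results that follow stand out because the effect of hepcidin differed between 3 h and 1 h in limma's test of the difference itself, or because a signal appeared in probe sets outside the comparisons. The groups hold 3 arrays each, too few to look for an outlying array in the way used for larger groups.

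The effect of hepcidin differed between the times for 254 genes, and the named ones have adjusted p-values in limma from 2.77e-04 (Rnf144b) to 0.0484 (Slc11a2). It was more positive at 3 h, as a log2 difference, for Fpr2 (2.77), Cxcl3 (2.71), Slc7a11 (2.60), Tarm1 (2.39), Acod1 (2.28), Gpr18 (1.76), Fas (1.74), Gpr84 (1.68), Gbp5 (1.45), Herpud1 (1.42), Nos2 (1.37), Il1b (1.15), Clec4e (1.06), Tnfrsf1b (1.04), Cp (0.98), Sod2 (0.96), Tnip1 (0.96), Gbp2 (0.90), Cebpd (0.88), Icam1 (0.81), Traf1 (0.80), Nfkb2 (0.73), Slc11a2 (0.66) and Cd14 (0.57). It was more negative for Nfatc1 (-0.52), Nfkbia (-0.55), Junb (-0.66), Irf1 (-0.66), Foxo3 (-0.68), Btg2 (-0.72), Tob1 (-0.73), Irs2 (-0.77), Sesn1 (-0.79), Rgs2 (-0.88), Tnf (-0.92), Olfr111 (-0.97), Zfp36 (-0.997), Ier3 (-1.03), Gpr183 (-1.12), Abcd2 (-1.16), Arhgap25 (-1.18), Snx24 (-1.28), Lbh (-1.29), P2ry1 (-1.34), Rnf144b (-1.34), Fam214a (-1.37), Angptl4 (-1.41), Nfkbiz (-1.44) and Tnfsf9 (-1.78). Fpr2, Cxcl3, Gpr18, Gbp5, Nos2, Il1b, Cp and Cebpd had at least 1 group below the array median of 4.87, near background, so the size of their difference is inexact. Icam1, Nfkbia, Rgs2 and Arhgap25 lost the call without at least 1 array, as did Tnf, Gbp5, Cp, Nfkb2, Slc11a2, Cd14, Nfatc1, Junb, Irf1, Foxo3, Btg2, Irs2 and Ier3. By list, the median difference was -0.27 for immediate early genes, 0.57 for inflammatory effectors and receptors, 0.073 for NRF2 genes, 0.16 for ER stress genes and -0.34 for FOXO targets.

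Of 100 splits of the arrays, 5 gave at least the 254 genes of the real one, and the highest other split gave 1330. That split left all 6 hepcidin arrays in place and exchanged the times of all PBS arrays. It therefore tests the sum of the time differences in hepcidin and in PBS. The splits with 350, 401 and 277 genes also left all 6 hepcidin arrays in place. Such splits keep the time difference among the hepcidin arrays whole, so their share cannot decide on chance for this count, which stays open. For the averaged effect 1 of 100 splits, the real one with 988 genes, gave as many, which is the smallest share that 100 splits can give. The highest other gave 526, and it left all 6 arrays of 3 h in place, so it kept the effect at 3 h whole. The splits take the arrays as independent, which no label states, so chance is made less likely for this count but not excluded. The 10 splits of 6 arrays are too few for a share under 0.05, and the real split, 1 of the 10, gave 138 genes at 1 h, 1316 at 3 h and 111 between the PBS groups against 0 in the highest other each time.

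Hepcidin raised NF-kB and inflammatory genes at both times, with Cxcl2, Tnf, Il1b and Nfkbia among them, and a contaminant of the wells is the technical explanation to weigh. Granulocytes among the hepcidin cells of 1 h are argued against by S100a8 and S100a9, which are abundant in granulocytes. These 2 genes changed by -0.022 on average at 1 h (SE 0.16), from 4.28 to 4.26 on the log2 scale, below the array median of 4.87. This test did not cover the cells of 3 h. Bacterial lipopolysaccharide in the peptide preparation cannot be told apart from the peptide, because no well had inactivated peptide or an endotoxin control: 7 of 30 type I interferon response genes, the arm of the response that a lipopolysaccharide receptor engages through TRIF, rose at 3 h. Ifnb1 changed by 0.18 (limma adjusted p = 0.353), and a low dose or early times may leave that arm weak, so the value decides for neither side. A direct effect of hepcidin on the macrophages stays open as the biological explanation.

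Far more genes fell at 3 h than at 1 h, 624 against 8, and for 107 of the 624 the larger fall at 3 h passed in the test of the difference. The 8 were 3 without PBS 1 h replicate 1, PBS 1 h replicate 2 or hepcidin 1 h replicate 2, 17 without hepcidin 1 h replicate 1, 2 with only the groups compared and 19 with array weights. A shift of whole arrays left by the normalization is argued against, because 529 genes still fell after median centring and 694 after quantile normalization. The median change of all genes at 3 h was 0.016 before either step, so both had little to correct. Values from before the deposited normalization were not tested, so falls that it may itself have made are not covered. A single array of the hepcidin group is argued against as the whole cause, because 395 fell without hepcidin 3 h replicate 3, although the number also dropped without PBS 3 h replicate 2 (358) or PBS 3 h replicate 3 (354). A later phase of the response in which genes such as Rnf144b, P2ry1 and Klf2 are turned down may explain it, as a hypothesis found and tested on the same data.

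Outside the comparisons, 754 probe sets that are not named here were tested as an alternative. With hepcidin, 3 of them passed at 1 h and 54 at 3 h, 27 higher and 27 lower, which is 7.16% of them at 3 h beside 5.36% of the named genes. They were not analysed further.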

How the results depend on the processing

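The STAT3 list without shared members was tried after the data had been seen, and the other alternatives were planned. No gene and no list past the threshold reversed its direction, but the balance of genes higher and lower did where it lay near 50%. Leaving out 1 array at a time gave 99 to 139 genes at 1 h, 837 to 1287 at 3 h, 736 to 996 for the average, 141 to 234 for the difference between times and 23 to 126 between the PBS groups; r between the times was 0.417 to 0.459, and 83 to 112 genes were higher at both times. Lists past the threshold then numbered 7 to 11 at 1 h, 7 to 10 at 3 h, 8 to 11 for the average, 4 to 6 for the difference and 4 to 9 between the PBS groups. Of the other alternatives, the following moved a count by more than 1.5 times, and the cause was not tested unless given. With only the groups compared, 805 genes passed at 3 h and 7 between the PBS groups, where fewer arrays estimate the spread. A change of at least 1.5-fold, a stricter threshold by construction, left 480 at 3 h, 229 for the average and 42 between the PBS groups, and an adjusted p under 0.1, a looser one, gave 391 for the difference and 248 between the PBS groups. A trended and robust prior gave 433 and 319 for those 2 comparisons and genes above the median mean 412 and 333, where fewer genes were tested. Between the PBS groups median centring gave 64 and array weights 285. Genes above the median mean also gave r = 0.574 between the times. For lists, an estimated correlation left 4 at 3 h and 1 between the PBS groups, fry left 1 there and genes above the median mean 4, and ranks left 5 at 1 h and 3 for the difference. The share of genes higher at 3 h, 52.6%, was 49.6% with a trended and robust prior and 48.0% above the median mean. The share with a more positive difference, 50.8%, was 41.9% with median centring, 45.1% above the median mean, 47.1% with a trended and robust prior, 49.5% with array weights and 49.4% at an adjusted p under 0.1, and 47.8%, 49.5% and 44.7% without PBS 1 h replicate 3, PBS 3 h replicate 1 or hepcidin 3 h replicate 2. The share higher between the PBS groups, 45.9%, was 53.6% with a trended and robust prior, 53.2% above the median mean, 54.4% with array weights, 57.1% with only these groups, 50.8% at an adjusted p under 0.1, and 53.3% and 50.5% without PBS 1 h replicate 3 or hepcidin 3 h replicate 1. Over all arrays left out in turn, tests of the genes that the naming rule chose kept their side of the threshold 4371 times, lost the call 434 times and gained one 7 times, and list tests 1546, 33 and 41 times. The mean of a gene's probe sets was not run, since each gene has 1. Signal near background limits dim genes: the array median was 4.87, and Il6 lay near 3.05 in PBS at 1 h.

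With the replicate number as a block, 163 genes passed at 1 h (132 of them shared with the 138), 1615 at 3 h (1280 shared), 1193 for the average (936), 348 for the difference (236) and 240 between the PBS groups (109). Deviations from the group means correlated above 0.1 in 4, 2 and 3 of the 6 pairs of arrays numbered 1, 2 and 3, which is not every pair, and no label says what the number marks. The numbers were therefore not taken to pair the arrays, and whether arrays of 1 number share a preparation stays open. The block put 49.7% of the genes higher at 3 h and 48.6% of the differences on the positive side. As a hint from the data and not the design, 10 of 12 arrays correlated best with their own number. The block gave 6 list tests a call and took none, and among the genes that the naming rule chose it gave 16 and took 4, those of Kcng2 and Mir3070b at 1 h, Irf4 for the average and Slc11a2 for the difference.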

Other observations

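The tests of receptor genes and of pseudogenes in this part were chosen after the result was seen. Hepcidin changed an unusual share of a set of genes for G protein-coupled receptors at 3 h. The set was picked by gene name and left out the olfactory, vomeronasal and taste receptor families. Of 1400 genes of those families 2 fell and 8 rose at 3 h, at a median expression of 3.00. Among genes above the median mean, 28 of 84 receptor genes passed, 33.3%, against 1201 of all 12337, or 9.73% (odds ratio 4.72, Fisher's exact test across genes, p = 2.45e-09; genes are not independent replicates). A filter that the change itself helps a gene to pass is argued against by a filter on the PBS arrays of 1 h. The 3 h comparison does not use these arrays, and 26 of 83 passed with that filter (odds ratio 4.35, Fisher's exact test, p = 3.18e-08). With no filter 32 of 234 of the set passed, 13.7% against 5.33% (odds ratio 2.86, smaller, Fisher's exact test, p = 9.99e-07). This last share depends on leaving out the families named above. Of the 28, 15 rose and 13 fell. Among the rises were 4.29 for Gpr84, 3.41 for Fpr2, 2.21 for Hcar2, 2.20 for Gpr18 and 1.55 for Ccrl2 on the log2 scale, and among the falls -1.47 for P2ry1, -1.27 for Gpr183, -1.19 for Lpar6, -1.10 for S1pr1 and -0.88 for Cnr2. Related receptors went both ways, with Lpar1 at 0.58 and Lpar4 at 0.57, although both of these lost the call without at least 1 array. Of the 84, 4 had passed at 1 h and 2 between the PBS groups. A turnover of receptors may be a feature of the response, as a hypothesis found and tested on the same data.

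Annotated pseudogenes, those annotated as transcribed left out, fell more often than they rose at 3 h, 28 against 2 of 510. Their median log2 change was -0.073, and already -0.068 at 1 h. Of 10000 random sets matched on mean expression 0.02% held as many falls, with 14 in the median set and 31 in the highest. With the transcribed ones included, 35 of 837 fell and 5 rose, at a median log2 change of -0.034. Random sets matched to these held 18 falls in the median set and 34 in the highest. These draws treat genes as independent, but pseudogenes above the array median moved together between arrays. At 3 h their mean was 7.755, 7.929 and 7.841 on the PBS arrays and 7.705, 7.666 and 7.550 on the hepcidin arrays. The share of random sets is therefore too small by an unknown amount, and chance was not excluded. Less genomic DNA or unspecific signal on the hepcidin arrays cannot be told apart: 1400 olfactory, vomeronasal and taste receptor genes had a median change of 0.046, but they lie near the floor of the values, at a median of 3.00 against 5.36 for the pseudogenes, with little room to fall. Signal shared with the parent genes cannot be told apart: the parents had a median change of 0.059, but only 6 of the 28 pseudogenes have a parent that can be named, and 4 of these lie above the array median. No biological explanation was tested.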
